A study of Homo sapiens with 9 samples.

How the data were processed

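RNA was sequenced from A375, a BRAF-mutant human melanoma cell line, in 3 groups of 3 libraries. Cells carried a control hairpin (shControl) or 1 of the hairpins shCCDC50-1 and shCCDC50-2 against CCDC50, delivered by lentivirus and selected with puromycin for 7 days. Per the labels, RNA was extracted with Trizol and libraries followed standard Illumina protocols. The knockdown was checked by the authors with qRT-PCR and immunoblotting, which were not analysed here. The hairpin sequences, the strand of the libraries and the counting tool are not given in the sources used here.

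The authors named Trim Galore and HISAT2 with the hg38 genome build, without versions. The deposited table holds expected counts as whole numbers for 67130 genes in 9 libraries, not scaled to library size. On average 718 genes per library stood at a count of exactly 4, against 645 at 3 and 374 at 5. The variance between replicates was 7.08 times the mean in shControl, 6.76 times in shCCDC50-1 and 6.85 times in shCCDC50-2 for genes with mean counts of 10 to 20. Counts of 1 and 2 were commoner, at 1077 and 723 genes, and a count of 8 stood at 354 genes against 360 at 7. The variance also holds differences between replicates. A sequenced fragment may be worth about 4 counts, but these values do not settle it. Counting error computed from these values may therefore be understated. Library totals were 68183322 to 78353076 counts. A count of 0 was given a floor of 12 counts per library (3 fragments of 4 counts), which covers counting error only.

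Gene identifiers were matched to GENCODE release 29 for position, type, GC content, transcript length and 3' UTR sequence. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 20102 genes, TMM factors scaled the libraries, and 1 quasi-likelihood fit with a mean per group used all 9 libraries. Each contrast was tested with the quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over the 20102 genes. A gene was called at an adjusted p under 0.05. Expression is given as TMM-scaled CPM, as mean ± SD over 3 libraries, and log2 fold changes with their standard error. Replicate numbers are shared between groups. Across the 9 pairs of libraries with the same number, within-group deviations correlated between -0.331 and 0.233, and 2 of 9 libraries correlated best with a library of their own number, so no pairing was modelled.

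The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named CCDC50. From genes called the same way with both hairpins it took the 12 largest rises and 12 largest falls by the smaller of both changes. It also took the 5 largest in each direction for each contrast, with a mean of at least 5 CPM and a gene symbol throughout. It added up to 4 called members of each list, and 16 lysosomal, autophagy and innate sensing genes whatever their values. Genes outside the rule are identified in the text. Named genes that overlap another tested gene are not all marked as such.

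The 27 lists covered the lysosome (hydrolases, membrane proteins, proton pump), autophagy (formation machinery, receptors with damage response), mTORC1 and TFEB sensing, and immunity (interferon, NF-kappaB, MHC class I). They also covered stress and metabolism (ER chaperones, integrated stress response, NRF2, cholesterol, glycolysis with hypoxia, mitochondrially encoded proteins, cytosolic ribosomal proteins), growth and death (G1/S, G2/M, p53, apoptosis, MAPK output) and melanoma state (melanocyte, invasive). Library composition RNAs and markers of epithelial, fibroblast and blood or endothelial cells completed them. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 54 tests against shControl and over 27 tests between the hairpins. Each was repeated with an estimated correlation and with fry. The number of called members is also given adjusted over the list alone.

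Alternatives were DESeq2 1.42.0, size factors by RLE or upper quartile, no filter on low counts or a CPM of at least 1 in 3 libraries, the replicate number as a block, only the libraries of the groups compared, stricter thresholds, and leaving out each library. Dividing counts by 4 and removing each library's trend with GC content and transcript length (splines through an offset, 98.1% of tested genes annotated) were chosen after seeing the data. Both hairpins share their controls, so the overlap of calls was set beside 20 simulated data sets with no change in any group. Genes were drawn independently in these data sets. All 9 libraries were kept. Within-group Spearman correlations were 0.983 to 0.986.

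The procedure was tested on simulated data with the genes' own means, dispersions and library sizes. Among planted genes with at least 5 CPM it recovered 9 of 22 at 1.5-fold, 28 of 29 at 2-fold and 23 of 23 at 3-fold for shCCDC50-1, and 10 of 22, 27 of 29 and 23 of 23 for shCCDC50-2. Over all 50 genes planted at each fold, whatever their CPM, it recovered 9, 29 and 29 for shCCDC50-1 at 1.5-, 2- and 3-fold. For shCCDC50-2 these were 10, 28 and 30. It made 3 and 8 calls outside the planted genes. A planted list shift of 0.2 was recovered with a camera adjusted p of 4.3e-14 at the preset correlation and 0.012 at the estimated one. Genes were drawn independently in these data. This recovery therefore does not show the power of the list test at the correlation of real genes. For hairpin seed effects, 16259 heptamers were scanned in the 3' UTRs of 10259 genes with at least 5 CPM. Each heptamer's z came from a regression of the log2 fold change on its presence, with 3' UTR length, its base content, transcript GC content and transcript length as covariates. The scan recovered 5 of 5 heptamers planted at -0.15 log2. Planted at -0.0438, the size estimated for the lowest heptamer with shCCDC50-2, 18 of 20 were the lowest and 12 passed the Bonferroni limit. It used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.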

Results

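Gene expression was measured by RNA sequencing in A375 melanoma cells carrying a control hairpin or either of 2 hairpins against CCDC50, with 3 libraries per group. Library totals were 78353076, 69399440 and 68183322 expected counts in shControl replicates 1, 2 and 3. They were 69316830, 71999176 and 70806469 in shCCDC50-1 and 70369613, 68780140 and 72240502 in shCCDC50-2. Replicate 1 of shControl lay farthest out on the principal component with the largest share of variance (16.5%), at -65.4, against -33.8 and -28.6 for the other controls. All p-values measure the spread between libraries only, since the labels do not say whether replicates were separate cultures or infections. The labels pose the question of how loss of CCDC50, whose product the series title links to lysosome homeostasis, alters expression in these cells.

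CCDC50 (ENSG00000152492, chromosome 3, 191329077 to 191398670, hg38) stood at 88.7 ± 4.40 CPM in shControl (SD, n = 3). It was 75.0 ± 3.91 CPM with shCCDC50-1 and 37.1 ± 4.11 CPM with shCCDC50-2. The transcript fell by 58.2% with shCCDC50-2, a log2 fold change of -1.26 (SE 0.09, edgeR adjusted p = 4.5e-05). With shCCDC50-1 the estimate was -0.24 (SE 0.09, edgeR adjusted p = 0.19) and did not pass the test, although each of its 3 libraries (71.5, 74.2 and 79.2 CPM) lay below each control (83.6 to 91.5 CPM). Of 3 against 3 libraries, 10% of genes would separate this way in 1 or the other direction by chance, while a knockdown predicts a fall only. The p-value was adjusted over all tested genes, although CCDC50 was the target named beforehand. Its unadjusted p is not given here. A loss of CCDC50 with this hairpin was therefore neither established nor excluded by these libraries. The authors checked the knockdown by qRT-PCR and immunoblotting, which were not analysed here. The labelling of this hairpin could not be checked here. CCDC50 differed between the hairpins by -1.02 (edgeR adjusted p = 1.3e-04). With the trend in GC content and length removed, the estimate for shCCDC50-1 was -0.08.

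**Figure D1:**
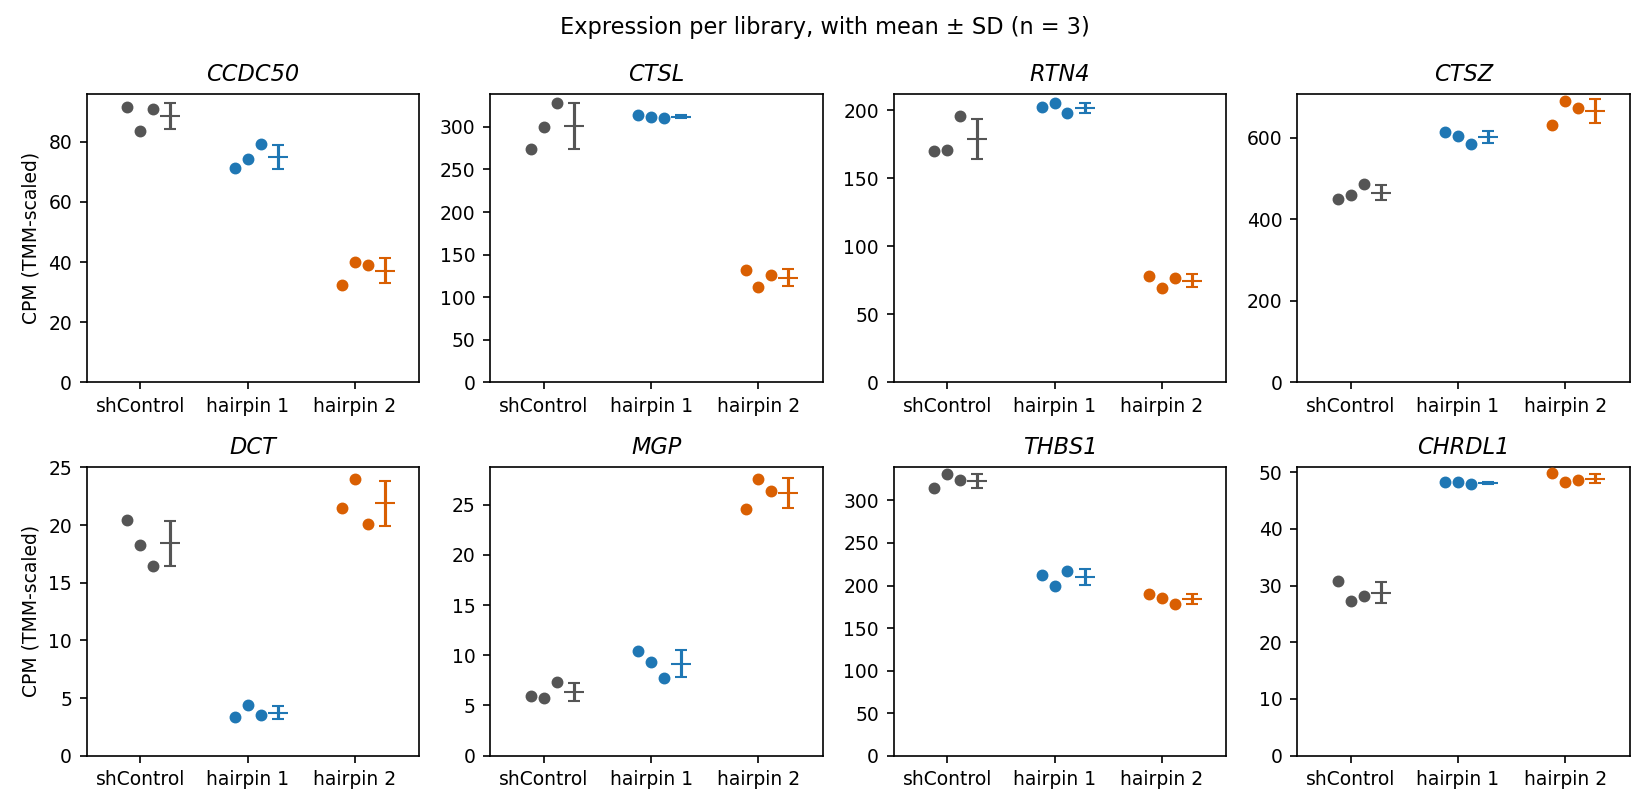
Expression of 8 genes in TMM-scaled CPM (vertical axis, from 0) for each of the 9 libraries, grouped by hairpin. Points are libraries and the bars beside them are mean ± SD (n = 3). CCDC50 is at 37.1 CPM with hairpin 2 and at 75.0 CPM with hairpin 1.

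The comparison with both hairpins asks which genes changed whichever hairpin was used. Among the rises were CHRDL1, a secreted antagonist of bone morphogenetic proteins, and assembly factors of the mitochondrial respiratory chain, NDUFAF8 and TTC19. CHRDL1 went from 28.8 ± 1.84 CPM to 48.2 ± 0.142 with shCCDC50-1 and 48.9 ± 0.795 with shCCDC50-2, log2 fold changes of 0.74 and 0.77 (edgeR adjusted p = 2.8e-04 and 2.4e-04). NDUFAF8 rose by 0.70 and 0.65, and TTC19 by 0.59 and 0.57, though TTC19 overlaps NCOR1 and ZSWIM7 on the other strand. The falls included DKK1, a secreted Wnt antagonist, THBS1, a matrix glycoprotein, the interleukin 7 receptor gene IL7R and the keratin gene KRT81.

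THBS1 went from 323 ± 8.56 CPM to 210 ± 9.39 and 185 ± 5.83, log2 fold changes of -0.62 and -0.81 (edgeR adjusted p = 2.6e-04 and 4.5e-05). DKK1 fell by 1.77 and 0.88 on the log2 scale, IL7R by 0.79 and 1.17, and KRT81 by 1.16 and 0.76. KRT81 overlaps KRT86, a related keratin gene. These 7 genes kept both calls whichever library was left out. The keratin genes KRT7 and KRT80, AJUBA, a LIM-domain adaptor, COL13A1, a transmembrane collagen, and CENPE, a mitotic kinesin, fell with both hairpins, by 0.63 to 1.41 on the log2 scale, while the keratin gene KRT10 rose with both (0.47 and 0.47). COLEC12, a scavenger receptor, TESC, SERPINF1, RPP25, PCDH7, NAT8L, ANTKMT and the noncoding LERFS rose with both, as did AL049839.2, which overlaps SERPINA3 on the same strand. The 12 largest falls among genes with at least 5 CPM also held CCDC15 and the noncoding AL161431.1 and MALAT1. Each of these 17 further genes, and KRT10, lost a call in at least 1 fit that left out a library, with adjusted p up to 0.20 (MALAT1, without shCCDC50-1 replicate 2).

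In all, 112 genes were called the same way with both hairpins, 72 higher and 40 lower, and 7 in opposite directions. The balance of rises and falls was not stable: it was 275 and 329 with DESeq2, 53 and 51 with GC and length trends removed, 14 and 18 with only the libraries compared, and 221 and 232 without shControl replicate 3. Simulated data with shared controls and no change gave a mean of 0.15 same-way genes (0 to 1), and lists drawn independently would share 2.96 higher and 3.22 lower. Across 11042 genes with at least 5 CPM, the log2 fold changes with both hairpins had a Pearson correlation of 0.671. It was 0.494 (0.447 to 0.550) in the simulated data, and genes are not independent replicates. The simulation drew genes independently and held no GC or length trend. Its count of same-way genes and its correlation may therefore be too low as a reference. Without shControl replicate 1, 2 or 3 the same-way count was 62, 29 or 453. It was 37, 24 or 49 without shCCDC50-1 replicate 1, 2 or 3, and 58, 20 or 32 without shCCDC50-2 replicate 1, 2 or 3. GC content and transcript length explained 35.7% and 36.9% of the variance of the log2 fold changes against shControl over 3853 genes with at least 50 CPM, and 6 of the 24 genes taken as the largest rises and falls with both (AL161431.1, ANTKMT, CCDC15, NAT8L, PCDH7 and TESC) lost a call with these trends removed. CTSZ, CRELD2 and TNC, also called higher with both, lost a call too (adjusted p = 0.12 and 0.067 with shCCDC50-1, and 0.22 with shCCDC50-2).

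**Figure D2:**
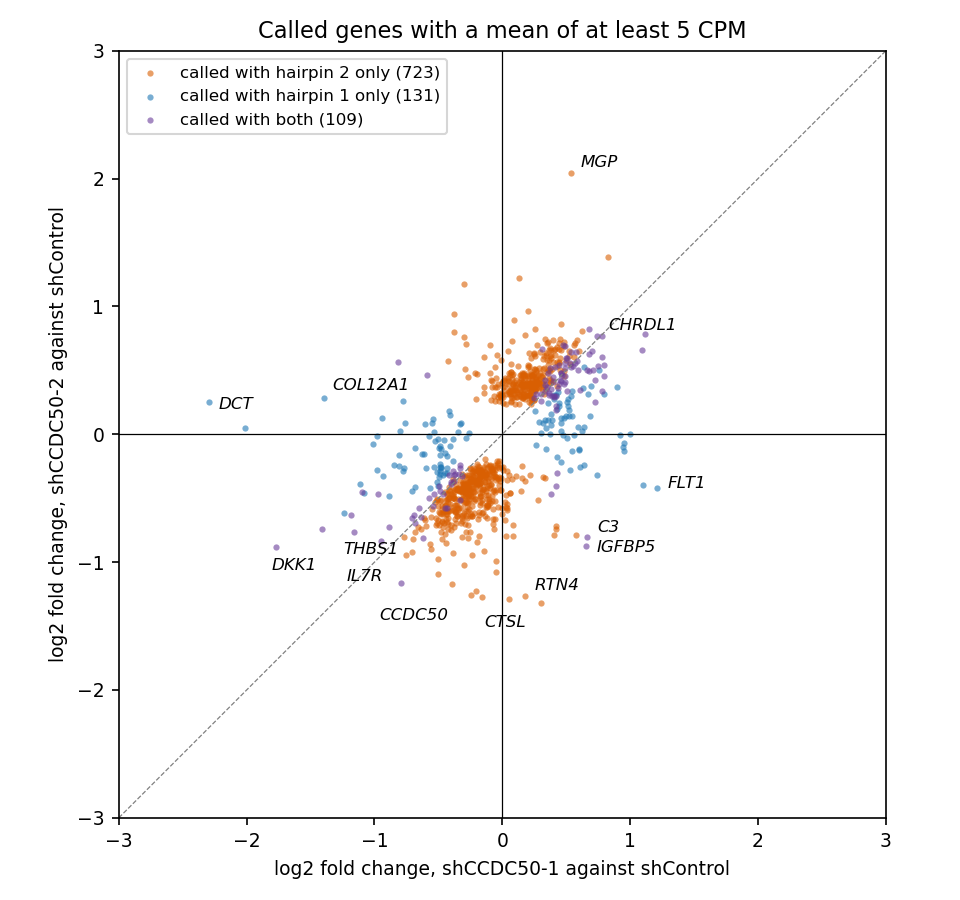
Log2 fold change against shControl with shCCDC50-1 (horizontal) and shCCDC50-2 (vertical) for called genes with a mean of at least 5 CPM, 1 point per gene and coloured by the hairpin with the call. Of these, 723 were called with hairpin 2 only, 131 with hairpin 1 only and 109 with both; 1 gene (AC007192.1) lies outside the plotted range of 3.

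With shCCDC50-1, the comparison asks what this hairpin changed against the control hairpin. The largest falls among genes with at least 5 CPM were in DCT, the dopachrome tautomerase of melanin synthesis, IL24, a secreted cytokine, DKK1, KRT7 and COL12A1, a fibril-associated collagen. DCT went from 18.4 ± 1.97 to 3.74 ± 0.546 CPM, a log2 fold change of -2.30 (SE 0.13, edgeR adjusted p = 2.3e-05). IL24 went from 14.1 ± 0.714 to 3.49 ± 0.955 CPM (-2.01, SE 0.17, edgeR adjusted p = 2.0e-04) and COL12A1 from 36.3 ± 2.79 to 13.8 ± 0.923 CPM (-1.39, SE 0.09, edgeR adjusted p = 2.5e-05). The largest rises included FLT1, a receptor for vascular endothelial growth factor, from 19.1 ± 0.440 to 44.2 ± 2.97 CPM (1.21, SE 0.11, edgeR adjusted p = 2.6e-04). COLEC12 rose 2.17-fold, TESC 2.14-fold and the noncoding LINC00540 2.14-fold.

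Genes of the invasive melanoma list moved in both directions with shCCDC50-1: 3 of 25 members were called higher and 6 lower (7 and 7 adjusted over the list alone). CCN2, a matricellular protein, fell by 1.08 and THBS1 by 0.62 on the log2 scale, while TGFBI rose by 0.56 and TNC, which encodes tenascin C, by 0.42. The list as a whole did not pass camera (median -0.02, adjusted p = 0.71). A further large rise, in AC007192.1 (5.75, edgeR adjusted p = 0.049), rested on shCCDC50-1 replicates 1 and 3 at 107 and 168 CPM against 2.24 CPM in replicate 2. This gene overlaps PIK3R2 and IFI30, and its call held in 2 of the 9 fits that left out a library (adjusted p up to 0.16, without shControl replicate 2).

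With shCCDC50-1, 272 of 20102 genes were called, 146 higher and 126 lower, of which 43 changed at least 2-fold (13 higher, 30 lower); 3357 had an unadjusted p under 0.05, and DESeq2 called 1125. The count was 171, 96 or 721 without shControl replicate 1, 2 or 3. It was 89, 73 or 130 without shCCDC50-1 replicate 1, 2 or 3, and 174, 148 or 163 without shCCDC50-2 replicate 1, 2 or 3.

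With shCCDC50-2, the hairpin with the clear loss of CCDC50, the comparison asks what changed against the control hairpin. The largest rises among genes with at least 5 CPM were in MGP, SOD3, APOE, ITIH5 and HTRA1. MGP, the matrix Gla protein, went from 6.34 ± 0.914 to 26.2 ± 1.5 CPM, a log2 fold change of 2.05 (SE 0.14, edgeR adjusted p = 4.4e-05). SOD3, the extracellular superoxide dismutase, rose by 1.39, APOE by 1.23, ITIH5 by 1.18 and HTRA1, a secreted serine protease, by 0.96. CTSL, which encodes cathepsin L (ENSG00000135047, chromosome 9, 87725519 to 87731393), went from 301 ± 27.1 to 123 ± 9.86 CPM, a log2 fold change of -1.29 (SE 0.08, edgeR adjusted p = 1.7e-05). RTN4, an endoplasmic reticulum membrane protein gene (ENSG00000115310, chromosome 2, 54972187 to 55112621), went from 179 ± 14.7 to 74.5 ± 4.67 CPM (-1.26, SE 0.07, edgeR adjusted p = 1.7e-05).

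The 3' UTRs of CTSL and RTN4 carry 1 and 2 copies of the heptamer TCATCTT, as do those of IL7R (1) and THBS1 (2). Among genes that rose with this hairpin, HTRA1, RRAGA and COL1A2 carry 1 copy each, while CALB2 and CXCL8, which fell, carry 0. CALB2, which encodes calretinin, fell by 1.27 and the chemokine gene CXCL8 by 1.32 on the log2 scale. The CXCL8 call held in 4 of the 9 fits that left out a library (adjusted p up to 0.14, without shCCDC50-2 replicate 2) and ended with GC and length trends removed (0.067). The calls for MGP, SOD3, APOE, ITIH5, HTRA1, CTSL, RTN4, CALB2, IL7R and THBS1 held in all 9. Of the 87 calls of named genes with this hairpin, 25 held in all 9 fits and 34 ended with GC and length trends removed. With this hairpin 921 genes were called, 408 higher and 513 lower, of which 73 changed at least 2-fold (27 higher, 46 lower); 4376 had an unadjusted p under 0.05, and DESeq2 called 2334. The count was 455, 235 or 1790 without shControl replicate 1, 2 or 3. It was 613 or 424 without shCCDC50-1 replicate 1 or 2, and 436, 94 or 150 without shCCDC50-2 replicate 1, 2 or 3.

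The lysosomal lists address the subject of the series title. Transcripts of lysosomal hydrolases were higher with shCCDC50-2: 39 of 48 members had a positive change, 8 were called higher and 1 lower (12 and 1 adjusted over the list alone). The median log2 fold change was 0.22 (camera adjusted p = 1.6e-05, and 0.39 with an estimated correlation). With fry the adjusted p was 0.023. CTSZ rose by 0.52, from 465 ± 18.3 to 666 ± 30.5 CPM (edgeR adjusted p = 8.4e-04), CTSF by 0.58 and CTSD, which encodes cathepsin D, by 0.48, while CTSL fell. With shCCDC50-1 the median was 0.08 (camera adjusted p = 0.015; adjusted p = 0.52 with an estimated correlation), with 38 of 48 members positive and CTSZ alone called (0.37; 3 higher and 0 lower adjusted over the list alone). That list call ended without shControl replicate 1 (0.045, adjusted p = 0.071) and with the GC and length trends removed (0.038, adjusted p = 0.18). The CTSZ call with shCCDC50-1 held in 7 of 9 fits (adjusted p up to 0.059, without shCCDC50-1 replicate 2); removing these trends ended it (0.12) and the CTSD call with shCCDC50-2 (0.094).

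Genes of the vacuolar proton pump, which acidifies the lysosome, and of lysosomal membrane proteins were also higher with shCCDC50-2. Of 17 pump subunits 16 had a positive change, median 0.19 (camera adjusted p = 0.0020; adjusted p = 0.31 with an estimated correlation); ATP6AP1 and TCIRG1 were called (3 and 0 adjusted over the list alone). Of 30 membrane proteins 24 were positive, median 0.17 (camera adjusted p = 0.011; adjusted p = 0.31 with an estimated correlation), and CLCN7, a lysosomal chloride exchanger, was called (0 and 0 adjusted over the list alone). The calls for ATP6AP1, TCIRG1 and CLCN7 each held in 1 of the 9 fits that left out a library, with adjusted p up to 0.164, 0.139 and 0.165 without shCCDC50-2 replicate 2, and ended with GC and length trends removed (0.093, 0.17 and 0.40). With fry the shCCDC50-2 adjusted p was 0.034 for the pump and 0.023 for the membrane proteins. With shCCDC50-1 neither list passed, with medians of 0.06 (camera adjusted p = 0.37) and 0.05 (camera adjusted p = 0.29). LAMP1 (0.25 and 0.29), LAMP2, CTSB, ATP6V1H and MCOLN1 passed the gene test with neither hairpin.

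Genes of mTORC1 and TFEB nutrient sensing were higher with shCCDC50-2, with 20 of 25 positive and a median of 0.17 (0.07 with GC and length trends removed). The list had a camera adjusted p of 0.0024, and 0.31 with an estimated correlation. With fry the adjusted p was 0.023. With shCCDC50-1 the median of the list was 0.02 (camera adjusted p = 0.47). RRAGA, a Rag GTPase, was its called member (6 and 0 adjusted over the list alone), in 3 of 9 fits (adjusted p up to 0.13, without shCCDC50-2 replicate 3), and not with GC and length trends removed (0.063). TFEB, a regulator of lysosomal genes, had estimates of 0.69 and 0.87 that did not pass (edgeR adjusted p = 0.17 and 0.055). With shCCDC50-2 it passed in 4 of 18 alternatives: with DESeq2, the stricter filter on low counts, counts divided by 4, and without shControl replicate 3 (adjusted p from 0.0062 to 0.14 over the 18). TFE3 and MITF did not pass either. The autophagosome machinery did not pass camera (medians -0.01 and 0.08, adjusted p = 0.97 and 0.27), but passed fry with shCCDC50-2 (adjusted p = 0.044), with 3 members called higher and 2 lower with shCCDC50-2 (5 and 4 adjusted over the list alone). ATG2A, WDR45 and GABARAP were the higher members. ATG3 was among the lower members (-0.25), and its call held in 6 of 18 alternatives (edgeR adjusted p up to 0.39). Autophagy receptors had medians of -0.09 and 0.00 (camera adjusted p = 0.074 and 0.71). With shCCDC50-1 the list passed when shControl replicate 2 was left out (0.031) and with no filter on low counts (0.034). With shCCDC50-2, CHMP4B, UBXN6 and CALCOCO1 were among 4 higher members and CCPG1 was lower (5 and 2 adjusted over the list alone). SQSTM1, MAP1LC3B and LGALS3 did not pass. WDR45 overlaps PRAF2 on the same strand and UBXN6 overlaps CHAF1A on the other strand, and both overlapping genes had higher total counts. Of the other named autophagy calls, ATG2A and CHMP4B held in 4 of 9 fits, WDR45 and CCPG1 in 3, CALCOCO1 and UBXN6 in 2 and GABARAP in 0. Their adjusted p reached 0.143 for CCPG1 without shCCDC50-2 replicate 3, and 0.108 (UBXN6) to 0.165 (GABARAP) for the others without shCCDC50-2 replicate 2. Removing GC and length trends ended the calls for ATG2A (0.18, with the change at 0.19 in place of 0.40), CHMP4B (0.092), GABARAP (0.12), UBXN6 (0.41) and WDR45 (0.17).

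**Figure D3:**
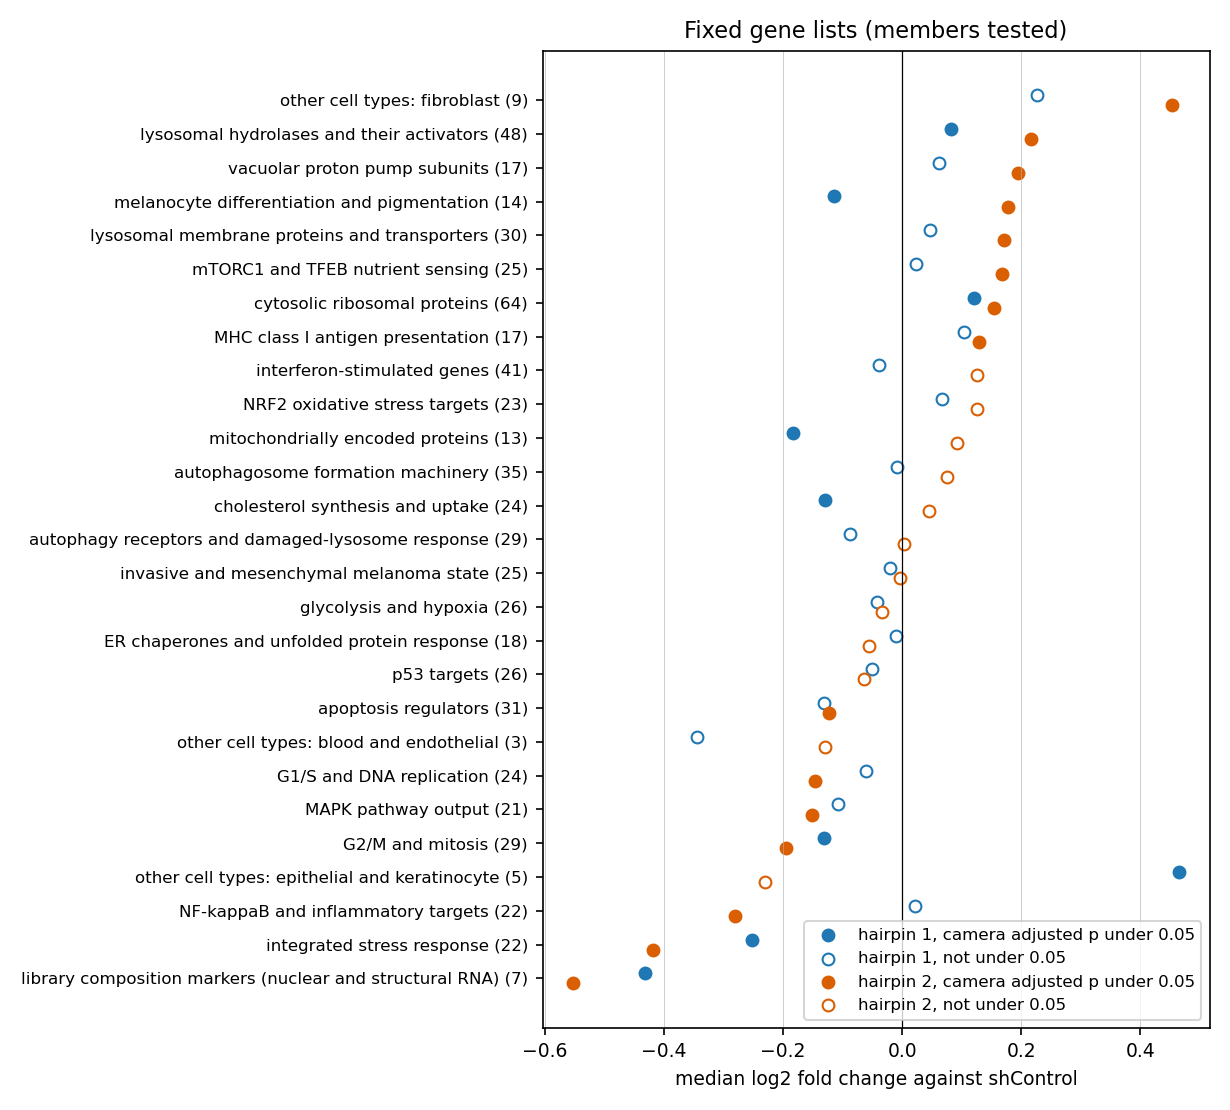
Median log2 fold change against shControl (horizontal) of the 27 fixed lists, with the number of members tested in brackets. Points are hairpin 1 or hairpin 2, filled at a camera adjusted p under 0.05 with the preset correlation; the lysosomal hydrolases are at 0.08 and 0.22.

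Several stress and growth lists were lower. The integrated stress response, the amino acid and stress program under ATF4, had a median of -0.42 with shCCDC50-2 (camera adjusted p = 1.7e-06; adjusted p = 0.52 with an estimated correlation) and -0.25 with shCCDC50-1 (0.015; adjusted p = 0.75 with an estimated correlation). With shCCDC50-2, ASNS fell by 1.02 and PSAT1, MTHFD2 and SLC7A11 by 0.56 to 0.79 (0 higher and 6 lower adjusted over the list alone). ASNS held in 7 of 9 fits and the other 3 in 4 (adjusted p up to 0.058, without shCCDC50-2 replicate 2, and 0.14, without shCCDC50-2 replicate 3), and MTHFD2 and SLC7A11 lost their calls with GC and length trends removed (0.057 and 0.086). The 3' UTRs of MTHFD2 and SLC7A11 carry 1 and 2 copies of the heptamer TCATCTT, and those of ASNS and PSAT1 carry 0. ASNS overlaps AC079781.5 on the same strand. With shCCDC50-1 the list lost its call without shCCDC50-1 replicate 1 (-0.09, adjusted p = 0.37), shControl replicate 2 (0.062) or shControl replicate 3 (0.099).

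Genes of DNA replication were lower with shCCDC50-2 (median -0.15, camera adjusted p = 6.0e-05; adjusted p = 0.52 with an estimated correlation), with 5 of 24 called lower (11 adjusted over the list alone). GINS1, a helicase component, fell by 0.91 and RRM2, a ribonucleotide reductase subunit, by 0.48, in all 9 fits. With shCCDC50-1 the median was -0.06 (adjusted p = 0.63). Mitotic genes had medians of -0.20 with shCCDC50-2 (camera adjusted p = 2.4e-05; adjusted p = 0.52 with an estimated correlation) and -0.13 with shCCDC50-1 (0.0024; adjusted p = 0.645 with an estimated correlation; 0.058 without shCCDC50-1 replicate 3). CENPE fell with both (-0.69 and -0.69), its calls held in 1 and 4 of 9 fits (adjusted p up to 0.19, without shCCDC50-1 replicate 1), and it was at -0.40 and -0.38 with GC and length trends removed. KIF11 and HMMR fell with shCCDC50-2 in 4 of 9 fits each (adjusted p up to 0.084 and 0.11, without shCCDC50-2 replicate 3). With GC and length trends removed KIF11 went from -0.34 to -0.15 (adjusted p = 0.43) and HMMR from -0.56 to -0.30 (0.088), and neither passed. Adjusted over the list alone, 12 mitotic genes were lower and 1 higher with shCCDC50-2, and 4 and 0 with shCCDC50-1. MAPK output had a median of -0.15 with shCCDC50-2 (camera adjusted p = 0.0027, and 0.58 with an estimated correlation). Without shCCDC50-2 replicate 2 it was -0.10 (0.059). With shCCDC50-1 the MAPK median was -0.11 and did not pass (camera adjusted p = 0.068). It passed without shCCDC50-1 replicate 3 (-0.23, 0.0037) or shControl replicate 1 (0.023), with GC and length trends removed (0.014) and with no filter on low counts (0.030). CCND1, which encodes cyclin D1, fell by 0.40 with shCCDC50-2 (2 lower adjusted over the list alone), in 7 of 9 fits (adjusted p up to 0.071, without shCCDC50-2 replicate 2). FOSL1, a transcription factor gene of this list, fell with both hairpins (-0.32 and -0.32, edgeR adjusted p = 0.046 and 0.026), in 1 and 5 of 9 fits (adjusted p up to 0.20, without shCCDC50-1 replicate 1, and 0.12, without shCCDC50-2 replicate 2).

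Inflammatory NF-kappaB targets were lower with shCCDC50-2 (median -0.28, camera adjusted p = 0.011; adjusted p = 0.59 with an estimated correlation), with CXCL8, CXCL1, IL1A and TRAF1 called (5 lower adjusted over the list alone). CXCL1 and TRAF1 held in 5 of 9 fits (adjusted p up to 0.11, without shCCDC50-2 replicate 2) and IL1A in 3 (0.15, without shCCDC50-2 replicate 3; 0.077 with GC and length trends removed). The list call ended without shCCDC50-2 replicate 2 (-0.16, adjusted p = 0.085) or shControl replicate 3 (-0.25, adjusted p = 0.056), and with shCCDC50-1 the median was 0.02 (adjusted p = 0.63). Interferon-stimulated genes did not pass (adjusted p = 0.87 and 0.14; with shCCDC50-2, 0.012 without shCCDC50-2 replicate 3, 0.037 without shControl replicate 1 and 0.033 with GC and length trends removed), with medians of -0.04 and 0.13. IFIT3 rose by 0.48 with shCCDC50-2 in 5 of 9 fits (adjusted p up to 0.13, without shCCDC50-2 replicate 2), while the RNA sensors IFIH1 and DDX58 did not pass. MHC class I genes were higher with shCCDC50-2 (0.13, camera adjusted p = 0.028, and 0.52 with an estimated correlation). With shCCDC50-1 their median of 0.10 did not pass (camera adjusted p = 0.068). It passed without shCCDC50-1 replicate 3 (0.042) or shControl replicate 3 (0.029), and with no filter on low counts (0.022). The shCCDC50-2 call ended without shControl replicate 1 (0.076), shCCDC50-2 replicate 2 (0.059) or shCCDC50-2 replicate 3 (0.061). It also ended with the stricter filter on low counts (0.054) and with GC and length trends removed (median 0.02, camera adjusted p = 0.31).

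The hairpins moved the melanocyte list in opposite directions, down with shCCDC50-1 (median -0.11, camera adjusted p = 0.0018; adjusted p = 0.22 with an estimated correlation) and up with shCCDC50-2 (0.18, camera adjusted p = 8.5e-04; adjusted p = 0.22 with an estimated correlation). Over the alternatives these medians ran from -0.22 to -0.05 and from 0.10 to 0.24. With fry the list had an adjusted p of 0.0014 with shCCDC50-1 and 2.6e-04 with shCCDC50-2. GPNMB, a melanosomal and lysosomal glycoprotein, rose by 0.71 with shCCDC50-2, along with SOX10 and S100B (4 higher adjusted over the list alone), and DCT fell with shCCDC50-1 (4 lower adjusted over the list alone). SOX10 overlaps POLR2F on the other strand. The calls for SOX10 and S100B held in 4 and 3 of 9 fits (adjusted p up to 0.098, without shCCDC50-2 replicate 3, and 0.13, without shCCDC50-2 replicate 2), and ended with GC and length trends removed (0.26 and 0.060).

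Ribosomal protein genes were slightly higher with both hairpins, with medians of 0.12 (camera adjusted p = 3.8e-06; adjusted p = 0.52 with an estimated correlation) and 0.15 (8.4e-09; adjusted p = 0.52 with an estimated correlation) and 0 and 15 of 64 members higher adjusted over the list alone. With GC and length trends removed these medians were 0.05 and 0.09. Mitochondrially encoded genes were lower with shCCDC50-1 (-0.18, camera adjusted p = 0.015; adjusted p = 0.70 with an estimated correlation). That call ended without shControl replicate 1 (-0.02, adjusted p = 0.70) or shCCDC50-1 replicate 3 (0.13). With shCCDC50-2 the median of 0.09 did not pass (0.068), but passed without shControl replicate 1 (0.24, adjusted p = 1.8e-09) or shCCDC50-2 replicate 1 (0.023), or with GC and length trends removed (0.014). It also passed with no filter on low counts (camera adjusted p = 0.030). Without shControl replicate 3 the median was -0.09 (adjusted p = 0.81). Of the 13 members, 3 were called higher with shCCDC50-2 (3 and 0 adjusted over the list alone). The mitochondrially encoded genes took 3.80% of counts in shControl replicate 1 against 2.94% and 2.74% in the other controls. Cholesterol genes were lower with shCCDC50-1 (-0.13, camera adjusted p = 0.030; adjusted p = 0.52 with an estimated correlation), which ended without shCCDC50-1 replicate 3 (-0.07, adjusted p = 0.25) or shControl replicate 2 (-0.19, adjusted p = 0.062), and not with shCCDC50-2 (0.05, adjusted p = 0.63).

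Apoptosis regulators were lower with shCCDC50-2 (-0.12, camera adjusted p = 0.033; adjusted p = 0.31 with an estimated correlation), a call that ended without shControl replicate 2 (-0.08, adjusted p = 0.10) or 3 (0.058), shCCDC50-1 replicate 2 (0.056), or shCCDC50-2 replicate 2 (0.064) or 3 (0.078). The stricter filter on low counts also ended this call (camera adjusted p = 0.054). With shCCDC50-1 the median of the apoptosis regulators was -0.13 (adjusted p = 0.17). ER chaperones (-0.01 and -0.06), p53 targets (-0.05 and -0.06), glycolysis with hypoxia (-0.04 and -0.03), NRF2 targets (0.07 and 0.13) and the invasive list with shCCDC50-2 (0.00) did not pass, with adjusted p from 0.28 to 0.87. The glycolysis list passed with GC and length trends removed (-0.11 and -0.11, adjusted p = 0.0046 and 0.026). CRELD2, an ER stress gene, rose with both hairpins (0.49 and 0.51), in 3 and 6 of 9 fits (adjusted p up to 0.13, without shCCDC50-1 replicate 1, and 0.076, without shCCDC50-2 replicate 2); its shCCDC50-1 call ended with GC and length trends removed (0.067). Median, mean and test differed in sign for interferon, NRF2 and ER chaperone genes with shCCDC50-1, and for NRF2, glycolysis, invasive, epithelial and blood or endothelial genes with shCCDC50-2.

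Nuclear and structural RNAs used as composition markers were lower with both hairpins, -0.43 (camera adjusted p = 0.0044; adjusted p = 0.44 with an estimated correlation) and -0.55 (0.028; adjusted p = 0.52 with an estimated correlation; -0.12 and 0.076 without shControl replicate 1, -0.17 with GC and length trends removed, 0.059 without shCCDC50-2 replicate 2). MALAT1 fell by 0.70 and 0.65, in 2 and 3 of 9 fits (adjusted p up to 0.20, without shCCDC50-1 replicate 2, and 0.12, without shCCDC50-2 replicate 3). Of 9 fibroblast markers 8 were positive with shCCDC50-2 (0.45, camera adjusted p = 0.011; adjusted p = 0.31 with an estimated correlation), where COL1A2 was called at 3.48 CPM (adjusted p up to 0.11, without shCCDC50-2 replicate 3). With shCCDC50-1 their median was 0.23 (adjusted p = 0.29). Of 5 epithelial markers the median was 0.47 with shCCDC50-1 (camera adjusted p = 0.032; adjusted p = 0.31 with an estimated correlation), and -0.23 with shCCDC50-2 (adjusted p = 0.74). KRT10 rose by 0.47 with each hairpin (adjusted p up to 0.068, without shCCDC50-1 replicate 2, and 0.059, without shCCDC50-2 replicate 3). The epithelial call ended without shControl replicate 2 (0.14) or 3 (0.076) or shCCDC50-1 replicate 2 (0.060, with the median at 0.16) or 3 (0.061), and with the stricter filter (0.11, adjusted p = 0.098) or counts divided by 4 (0.11, adjusted p = 0.089). The 3 tested blood or endothelial markers did not pass (-0.34 and -0.13, adjusted p = 0.66 and 0.87).

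The direct comparison of shCCDC50-2 with shCCDC50-1, in which the controls drop out of the estimate but not of the error, asks where the hairpins differed. DCT was higher with shCCDC50-2 by 2.55, IL24 by 2.07, COL12A1 by 1.67, COL8A1, a short-chain collagen, by 1.57 and MGP by 1.51. FLT1 was lower with shCCDC50-2 (-1.63), as were CXCL8 (-1.62), IGFBP5, an insulin-like growth factor binding protein gene (-1.52), LINC00540 (-1.49) and C3, the complement component (-1.46). C3 overlaps GPR108 on the same strand. IGFBP5 went from 92.5 ± 3.38 CPM in shControl to 145 ± 13.9 with shCCDC50-1 and 50.6 ± 1.51 with shCCDC50-2 (edgeR adjusted p = 1.6e-06 between hairpins). The melanocyte list differed by a median of 0.29 (camera adjusted p = 1.0e-15; 0.0029 with an estimated correlation), and 12 of its 14 members were higher with shCCDC50-2.

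Of 20102 genes, 316 differed between the hairpins by the edgeR test, 152 higher and 164 lower with shCCDC50-2, of which 82 were at least 2-fold; 2323 had an unadjusted p under 0.05, and DESeq2 called 785. Of the 112 genes called the same way, 9 differed between the hairpins. GC content and length explained 3.54% of the variance of this contrast. The count was 473 with only the hairpin libraries. It was 594, 232 or 342 without shControl replicate 1, 2 or 3, 192, 145 or 175 without shCCDC50-1 replicate 1, 2 or 3, and 191, 150 or 159 without shCCDC50-2 replicate 1, 2 or 3. The CXCL8 difference held in 5 of 9 fits (adjusted p up to 0.12, without shCCDC50-2 replicate 2).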

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

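The comparison of effect sizes between the hairpins, the removal of GC and length trends and the reading of the hydrolase shares against 0.5 alone were chosen only after results were seen; the other tests in this part were set out beforehand.

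Expression differed between the hairpins themselves in 316 genes by the edgeR test. The log2 differences of shCCDC50-2 from shCCDC50-1 were -1.02 for CCDC50, 2.55 for DCT, 2.07 for IL24, 1.67 for COL12A1, 1.57 for COL8A1 and 1.51 for MGP. They were -1.63 for FLT1, -1.62 for CXCL8, -1.52 for IGFBP5, -1.49 for LINC00540 and -1.46 for C3. The CXCL8 difference ended without shCCDC50-2 replicate 2 (adjusted p = 0.12). List medians also differed by camera with the preset correlation: 0.29 for melanocyte genes, 0.27 for mitochondrially encoded genes, 0.14 for the proton pump, 0.13 for mTORC1 and TFEB sensing, 0.12 for lysosomal hydrolases, 0.12 for cholesterol genes and 0.095 for autophagy receptors. They were -0.28 for NF-kappaB targets, -0.19 for the integrated stress response and -0.13 for DNA replication. Only the melanocyte list passed with an estimated correlation (adjusted p = 0.0029); for the other 9 lists the adjusted p ranged from 0.27 to 0.63.

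The first pattern weighed is that the hairpins changed partly different genes, including 7 called in opposite directions. By the direct test, 85 of the 272 genes called with shCCDC50-1 and 145 of the 921 called with shCCDC50-2 differed between the hairpins. Of the 272, 18.4% had the opposite sign with shCCDC50-2. For the other calls, passing with 1 hairpin only does not show a difference. A weaker knockdown with shCCDC50-1 would have the 272 genes called with it move further with shCCDC50-2, but they moved less. The median ratio of their changes was 0.532 (bootstrap 95% bounds 0.466 to 0.604, by resampling genes and not libraries). In data simulated with equal effects it was 0.929 to 0.960. Picking genes called with shCCDC50-1 by itself lowers this ratio. The simulation planted only the changes called with shCCDC50-2 and drew genes independently, so it may understate this lowering. The reverse ratio over genes called with shCCDC50-2 was 0.553, as a weaker knockdown would also give. The ratios therefore do not decide, and a weaker knockdown stays open, though it alone would not give opposite calls. A seed effect of shCCDC50-2 is a candidate explanation for part of the difference, as the heptamer TCATCTT had a covariate-corrected z of -7.58 in 3' UTRs with this hairpin (highest z of any heptamer 3.95, Bonferroni limit 4.67) and 1.06 with shCCDC50-1. Without correction for length or GC content it was carried by 142 of 440 genes called lower (32.3%), CTSL and RTN4 among them. It was carried by 28 of 360 called higher (7.78%) and by 1701 of all 10259. Carriers were lower than other genes with shCCDC50-1 too (medians -0.07 and 0.02, against -0.10 and 0.03 with shCCDC50-2). Of 3 CCDC50 transcripts 2 hold the heptamer, though the CCDC50 3' UTR searched carries 0 copies. CCDC50 transcripts hold 36.7% of all heptamers. For shCCDC50-1 no heptamer passed (lowest z -4.41, highest 3.90), which leaves a seed effect open, as do the unknown hairpin sequences and an effect of the depth of CCDC50 loss on other genes.

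The next pattern is that shControl replicate 1 stood apart from the other controls. The SD of its deviation from them was 0.2358, and that of the difference between them was 0.1371. Each hairpin group also held a library that stood apart in this way. The same values were 0.2405 and 0.1138 for shCCDC50-1 replicate 3, and 0.2005 and 0.1098 for shCCDC50-2 replicate 1. Standing apart was therefore not particular to the controls, and its cause in the hairpin groups was not tested. The deviation of shControl replicate 1 had an SD 1.99 times that expected from the other controls. After its counts were thinned to their depth the value was 1.99 as well. Thinning adds counting noise and could not lower this SD, so the test does not decide on its larger library. GC content and transcript length explained 53.7% of the variance of its deviation and 15.5% of that between the other controls, so a difference in library preparation or RNA quality that follows GC content may contribute. This cannot be told apart from a difference peculiar to that library, since the other controls share some of the trend. No biological explanation was tested, because the labels give none for a single replicate.

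The last pattern is that lysosomal hydrolase genes were higher with shCCDC50-2. With GC and length trends removed the list median was 0.19, a share of 0.870 of the reported 0.22 (bounds 0.568 to 1.03, by resampling genes), and without shControl replicate 1 it was 0.17, a share of 0.782 (bounds 0.653 to 1.03). Either alone as the whole cause is argued against. The list passed camera at the preset correlation in both (adjusted p = 7.9e-04 and 1.0e-04), and both lower bounds exceed the 0.5 set beforehand as the mark of a cause. These bounds hold no spread between libraries. The trends and that library were not removed together, so their joint effect was not tested. The rule set beforehand was for the shares themselves, and both met its mark of 0.75 against a cause. Their lower bounds fall short of that mark, so a part stays open for each, as does an effect of this hairpin alone. A lysosomal response to CCDC50 loss may contribute. The list passed fry (adjusted p = 0.023) but not camera with an estimated correlation (adjusted p = 0.39). The hairpin shCCDC50-1 cannot test this response, as whether that hairpin lowered CCDC50, or was labelled correctly, is open.

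Other groupings of the libraries were tried for each count. With shCCDC50-1 against shControl the real split gave 272 genes and the highest of the others 0, as 1 of 10 splits. With shCCDC50-2 the values were 921 and 2, and between the hairpins 316 and 1, each as 1 of 10 splits; with 10 splits a share under 0.05 is out of reach. For genes called the same way with both hairpins, 70 of 840 possible splits of the 9 libraries were drawn. The real split was the only 1 with as many as 112, and the highest other gave 42. A chance assignment of libraries to groups is argued against, but not excluded. The test cannot tell an effect of both hairpins from any other difference of the shared controls.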

How the results depend on the processing

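Removing GC and length trends and dividing counts by 4 were chosen after seeing the data. No called result changed sign under any alternative, but the higher share of same-way genes was not stable and the uncalled mitochondrial median with shCCDC50-2 ran from -0.09 to 0.24. CCDC50 kept its side of the threshold with both hairpins in all 18 alternatives (-0.29 to -0.08 with shCCDC50-1, -1.31 to -1.09 with shCCDC50-2). RLE and upper-quartile factors, the stricter filter and counts divided by 4 left every main count within 1.5 times its value and the hydrolase list on its side of the threshold; of the other list results the stricter filter ended 3 calls and counts divided by 4 ended 1. Counts are given in the order shCCDC50-1, shCCDC50-2, between hairpins, same way with both: 272, 921, 316 and 112 as reported. DESeq2 gave 1125, 2334, 785 and 604; the cause was not tested. Without a filter on low counts they were 135, 386, 209 and 47, with 32613 genes tested. With the replicate number as a block they were 95, 229, 180 and 25, and with only the libraries compared 121, 368 and 32 (473 between hairpins); the cause was not tested. With at least 2-fold change they were 43, 73, 82 and 7, and at an adjusted p under 0.01 76, 93, 126 and 13, both by construction. With GC and length trends removed shCCDC50-2 gave 599, of which 441 were among the 921 reported. Of the reported calls, 205 of 272 with shCCDC50-1 and 301 of 316 between the hairpins were kept. The cause was not tested. Leaving out 1 library gave 73 to 721, 94 to 1790, 145 to 594 and 20 to 453, highest without shControl replicate 3 (replicate 1 between hairpins); the cause was not tested. With an estimated correlation 0 and 0 lists passed camera (2 and 6 at an unadjusted p under 0.05) in place of 9 and 15, and with fry 2 and 8. Those passing fry with shCCDC50-1 were the melanocyte and epithelial lists. With shCCDC50-2 they were the hydrolase, membrane protein, proton pump, autophagosome, mTORC1 and TFEB, apoptosis, melanocyte and fibroblast lists. The hydrolase list lost its call with both hairpins at the estimated correlation (0.081 and 0.22, adjusted p = 0.52 and 0.39). With shCCDC50-1 it also lost it with fry (0.081, adjusted p = 0.13), with the trends removed (0.038, adjusted p = 0.18) and without shControl replicate 1 (0.045 to 0.14 over all libraries left out); the cause was not tested. Of the named calls 22 of 42, 25 of 87 and 21 of 26 were kept whichever library was left out. A planted 1.5-fold change was recovered in 40.9% and 45.5% of genes with at least 5 CPM, and in 18% and 20% of all genes planted at that fold.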

Other observations

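The genes in this part were picked after their values were seen, except AKR1B10, IGFBP5 and C3, which the rule for named genes took.

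AKR1B10 (ENSG00000198074), which encodes an aldo-keto reductase that reduces retinal and other aldehydes, was not detected with either hairpin. It had 307, 223 and 270 counts in the controls (3.71 ± 0.449 CPM, SD, n = 3) and 0 counts in all 6 hairpin libraries. Against a floor of 12 counts per library it was at least 21.3-fold lower. It was the only gene with 0 counts in all 6 hairpin libraries and at least 30 in every control, and 0 genes showed the reverse. The median of the NRF2 list was the same with AKR1B10 at its bound (0.07 and 0.13), and the mean was -0.19 and -0.15 in place of -0.47 and -0.43.

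The 7 genes called in opposite directions fell into 5 that were higher with shCCDC50-1 and lower with shCCDC50-2, and the reverse for A2M and CITED2. The former were IGFBP5 (0.65 and -0.87), C3 (0.66 and -0.80), NEFL, a neurofilament gene (0.38 and -0.46), SOX11, a neural transcription factor gene (0.42 and -0.41), and HMGA2, a chromatin protein gene (0.43 and -0.30). C3 overlaps GPR108 on the same strand, with total counts of 20322 and 20244. A2M, which encodes a protease inhibitor, was at -0.81 and 0.56, and CITED2 at -0.59 and 0.46. All 7 differed between the hairpins by the edgeR test, with adjusted p from 1.6e-06 to 3.3e-04. IGFBP5 and A2M kept both calls against shControl whichever library was left out. Of the 9 fits that left out a library, the call with shCCDC50-1 held in 9 for CITED2, 8 for C3, 6 for HMGA2, 3 for SOX11 and 2 for NEFL. Its adjusted p reached 0.068 for C3 and 0.15 for SOX11 without shCCDC50-1 replicate 2, and 0.087 for HMGA2 and 0.19 for NEFL without shCCDC50-1 replicate 1. With shCCDC50-2 the call held in 9 for C3, 7 for NEFL, 6 for SOX11, 5 for CITED2 and 2 for HMGA2. There it reached 0.065 for NEFL, 0.11 for SOX11 and 0.071 for CITED2 without shCCDC50-2 replicate 2, and 0.15 for HMGA2 without shCCDC50-2 replicate 3. With GC and length trends removed, the HMGA2 call with shCCDC50-2 (0.60) and the NEFL call with shCCDC50-1 (0.051) ended.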
